A study of Mus musculus with 8 samples.

How the data were processed

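RNA of the tibialis anterior (TA), a fast muscle of the lower hind limb, was profiled in 8 libraries, 4 of the WT group and 4 of the KO group. Per the labels' protocols, RNA was isolated with TriZol and DNA was digested. Libraries were built, per the labels' protocols, on an Ion Chef robot with the Ion AmpliSeq Transcriptome Mouse panel, which reads 1 short amplicon per gene. The value of a gene is therefore the abundance of that amplicon, and a deletion changes it only where the amplicon or the stability of the transcript is affected. The position of each amplicon is not given in the sources used here.

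The authors deposited 1 table of RPM values, the reads of a target scaled by all reads of its library. It held 23930 targets and 1 column per library. Each column sums to the full scale of RPM, so each library was scaled to its own total of reads on targets. The submitters' processing notes name Transcriptome Analysis Console, without a version. The aligner, the genome build, the counting rule and any filter are not given in the sources used here. The columns were matched to samples by the barcode in the labels. No column belonged to another sample, and every target carried a gene symbol.

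The low RPM values in each library were whole multiples of the value of 1 read, so the reads were recovered by division. All values, 100.0% in each library, came within 0.1 of a whole read. The totals were 9119006, 7000920, 7513761 and 8208196 reads for WT1 to WT4, and 5983175, 7110832, 8079897 and 8639420 reads for KO1 to KO4. A level of 3 reads, taken as the floor of detection, corresponded to 0.329 to 0.501 RPM. Floors and intervals from reads cover counting error only, because the reads carry no molecular identifiers. No pair of libraries within a group agreed within sampling noise (chi-square per degree of freedom 12.26 to 34.36 over targets with at least 20 reads), and each was counted as 1 replicate. The labels speak of separate mice, and n below is the number of libraries per group.

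The groups were compared on log2(RPM + 1) for the 11004 targets with a mean of at least 1 RPM, with limma 3.58.1 in R 4.3.3, with variances moderated along an intensity trend. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg (BH) method over all tested genes, with a threshold of 0.05. Fold changes on this scale understate the change of genes near 1 RPM. This test had been chosen for RPM values, and the table held RPM. Sdhc was also tested with an exact permutation test.

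Before the data were examined, gene lists were fixed from textbook knowledge of energy metabolism, stress responses, muscle structure and the cell types of muscle, with large complexes added by symbol pattern (mitochondrial ribosome, cytosolic ribosome, proteasome). Lists with at least 5 tested members, 38 in all, were tested with limma's camera at a preset correlation of 0.01 between genes, which asks whether the members moved together more than other genes. The list p-values were adjusted by BH over the lists. The erythroid list had 1 tested member, and the list of genes encoded in mitochondrial DNA had 0 targets in the table used here. Members of a list that were not in the table used here were not analysed here. Camera was run again with the correlation estimated from the data, and fry, which tests each list alone, was run as a further alternative.

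The rule for named genes, also fixed at the same time, was as follows. All complex II genes were named. Among genes past the threshold, with at least 5 RPM in the higher group and no overlap between the groups, the 10 with the largest change in each direction were named. From each list described, up to 4 members past the threshold could be named, or else the 2 with the smallest p, and for other cell types also the 2 most abundant. Not every gene that this rule picked is given in the text. All genes named outside the rule, in the text or figures, were chosen after their values were seen. Lists of osteoblast and osteocyte, osteoclast and bone marrow granulocyte genes were written after the matrix genes had been seen.

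The alternatives tried were pseudocounts of 0.1 and 5 RPM, no filter and a filter at a mean of 10 RPM, median-ratio, TMM and quantile scaling, no intensity trend, library weights, the replicate number as a block, sex as a term, edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on the recovered reads, other thresholds, and leaving out each library in turn. Added after seeing the data were a comparison without WT1 and WT4 and a fit with a score of 7 bone genes as a covariate. Sex, which the labels do not state, was read from Xist and 4 Y-linked genes. By these genes, replicates 1 and 3 were male and replicates 2 and 4 female in both groups, so each group held 2 males and 2 females.

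The procedure was tested on simulated reads for the same 11004 genes and library sizes in 5 runs, and the changed genes were pooled over the runs. They were drawn only from genes with a mean of at least 5 RPM. Recovery of tested genes below 5 RPM was therefore not measured. At an adjusted p threshold of 0.05, limma recovered 19.2% of 250 genes changed 1.5-fold, 83.2% of those changed 2-fold, 99.6% of those changed 4-fold and all of those changed 8-fold, and 5.1% of its calls were false, against 4.5% for edgeR and 8.9% for DESeq2. The simulated list shift was called by camera in 5 of 5 runs, with 0 of 190 calls on the other lists. The simulated genes were drawn independently of each other. In the data the estimated correlation between genes was 0.772 for the matrix list and 0.593 for the slow fibre list. The simulation therefore cannot tell how often camera calls lists of correlated genes falsely. Gene positions were taken from the GENCODE vM21 annotation of GRCm38 by symbol, since the panel's own build is not given in the sources used here. Figures and tables were made with Python 3.11.15 and matplotlib 3.10.9.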

Results

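Gene expression in the TA muscle was measured in 4 WT and 4 KO mice. The KO mice carried an inducible Cre under a skeletal muscle actin promoter (HSA-Cre) together with loxP sites in Sdhc, the gene of a membrane subunit that anchors succinate dehydrogenase (SDH, complex II of the respiratory chain). The WT mice were littermates with the same Cre and no loxP sites. All mice received tamoxifen at 12 weeks of age, and the muscle was collected 3 weeks later. The series concerns complex II in muscle respiration, fatigue and muscle mass in emphysema, and this comparison asks how the muscle transcriptome differs 3 weeks after the loss of Sdhc. The libraries held 5983175 to 9119006 reads, 15055 to 15824 targets were above 0 per library, and the 10 most abundant targets took 17.75 to 25.47% of the reads.

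Sdhc, the targeted gene, was first examined in every library. Its amplicon stood at 737, 853, 848 and 748 RPM in WT1 to WT4 and at 16.9, 46.5, 18.7 and 54.3 RPM in KO1 to KO4, resting on 5973 to 6718 reads in the WT and 101 to 469 reads in the KO libraries. The mean fell 23.4-fold, from 797 ± 62.6 RPM (SD, n = 4) to 34.1 ± 19.1 RPM (SD, n = 4), and the KO libraries retained 4.28 ± 2.40% (SD, n = 4) of the WT mean. The log2 fold change was -4.68 (SE 0.31, limma with BH adjustment, adjusted p = 1.06e-05). An exact two-sided permutation test of the 8 values gave p = 0.0286, the smallest that 4 against 4 libraries allow. Sdhc (ENSMUSG00000058076.12) lies on chromosome 1, 171127165 to 171150603 on the minus strand (GRCm38). The position of the amplicon relative to the deleted part is not given in the sources used here. A target outside the deleted part would report the deletion only through the stability of the transcript. The 8 values of Sdhc went with the labels, and p-values of single genes below measure the spread between these animals. Camera's p-values at the preset correlation of 0.01 treat the genes of a list as nearly independent. They therefore do not stand for replication over animals. An exact permutation test over the 8 libraries, on the mean log2(RPM + 1) of a list, gave p = 0.0286 for matrix and 0.3143 for slow fibre genes.

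The other genes of complex II did not pass the test. Sdha, which carries the flavin, averaged 1196 ± 196 RPM in WT and 1339 ± 160 RPM in KO (SD, n = 4 each), with a log2 fold change of 0.17 and a 95% interval from -0.14 to 0.48. Sdhb, the iron-sulfur subunit, averaged 777 ± 149 and 835 ± 70.8 RPM (0.12, interval -0.20 to 0.45). Sdhd, the second membrane anchor and partner of Sdhc, averaged 845 ± 125 and 869 ± 94.7 RPM (0.05, interval -0.25 to 0.34). Among the assembly factors the log2 fold changes were -0.09 for Sdhaf1, 0.08 for Sdhaf2, 0.36 for Sdhaf3 and 0.14 for Sdhaf4. As a list, complex II had 1 of 8 members past the threshold, Sdhc, both over all genes and adjusted over the list alone, and camera placed the list at an adjusted p of 0.828 (BH over lists).

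**Figure D1:**
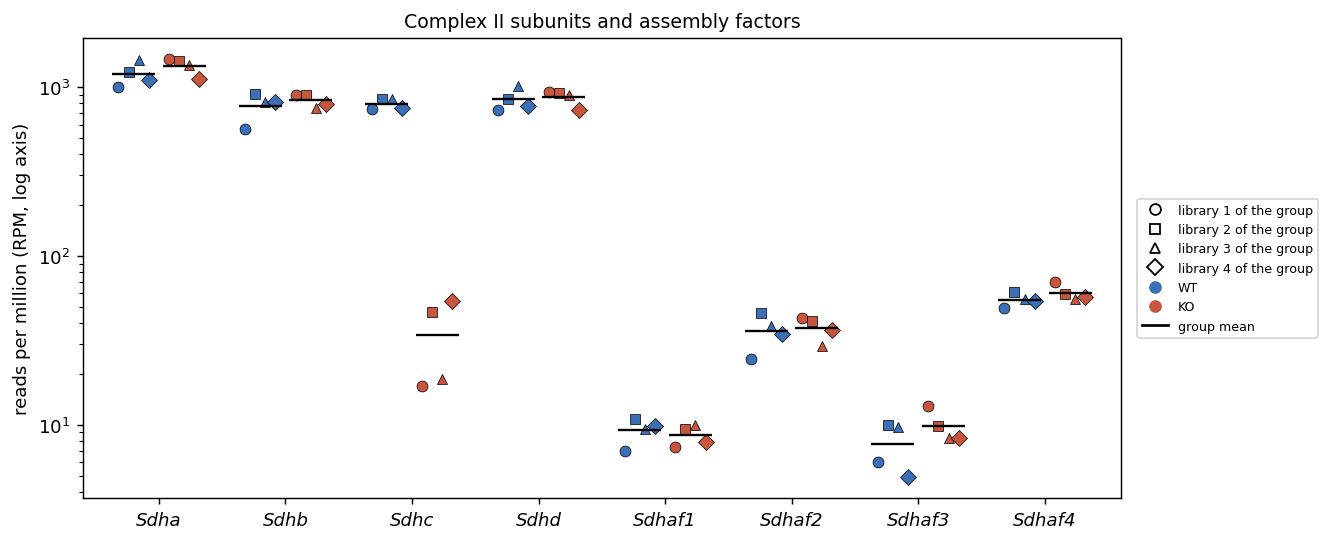
RPM on a log axis for the 4 subunits and 4 assembly factors of complex II, with 1 point per library, WT in blue and KO in red, and a black bar at each group mean. Sdhc is the only gene of the 8 whose groups are apart, at 737 to 853 RPM in WT and 16.9 to 54.3 RPM in KO, while the groups of the other 7 genes overlap.

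Across the transcriptome, 3 of 11004 genes passed the threshold, and all 3 fell in the KO. Besides Sdhc these were Gpx3, which encodes a secreted glutathione peroxidase, and Tgfb3, which encodes a transforming growth factor beta ligand. Gpx3 (chromosome 11, 54902453 to 54910377, plus strand) fell from 502 ± 88.6 to 236 ± 21.6 RPM (SD, n = 4 each), a log2 fold change of -1.07 (SE 0.14, limma with BH, adjusted p = 0.0218). Tgfb3 (chromosome 12, 86056745 to 86079041, minus strand) fell from 108 ± 13.8 to 58.4 ± 5.01 RPM (SD, n = 4 each), a log2 fold change of -0.87 (SE 0.13, limma with BH, adjusted p = 0.0403). In both genes all 4 KO libraries lay below all 4 WT libraries. Gpx3 stood at 536, 495, 384 and 593 RPM in WT1 to WT4. The score of 7 bone genes had the same order (4.264, 2.668, 2.001 and 5.101), but Gpx3 in the KO libraries did not follow it. Both calls were lost with that score as a covariate and without WT1 and WT4. The score separates the groups, so bone and genotype cannot be told apart for Gpx3 and Tgfb3. At an unadjusted p under 0.05, 1015 genes differed where 550 are expected by chance, 942 of them lower and 73 higher in the KO. Under other scalings this split was 730 lower and 383 higher (median ratio), 782 and 323 (TMM) and 582 and 420 (quantile). Some regroupings of the 8 libraries into 4 and 4 gave more genes at an unadjusted p under 0.05 (1765, 1194 and 1036). Those with 1765 and 1194 put WT1 and WT4, the libraries with the highest bone scores, on the same side, and that with 1036 did not. Chance could therefore not be excluded for the count of 1015. In 502 genes all KO libraries lay below all WT libraries and in 59 all lay above, together 5.1% of the genes where chance gives 2.86%. The calls of Gpx3 and Tgfb3 were lost in edgeR's quasi-likelihood test (adjusted p = 0.158 for both with BH; over all alternatives 1.83e-05 to 1 for Gpx3 and 0.000153 to 1 for Tgfb3), while Sdhc kept its call in every alternative run. DESeq2, for which 8.9% of calls were false in simulated reads against 5.1% for limma, called 149 genes, 145 of them lower. Limma called 130 without WT3 and 10 without KO1, against 1 when any of the other 6 libraries was left out.

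Genes of the extracellular matrix and of tendon were the groups that fell most. All 27 tested matrix genes had values below 0, with a median log2 fold change of -1.34 (limma camera, BH adjusted p = 6.92e-27; adjusted p = 0.417 with an estimated correlation). Over all genes 0 of the 27 passed in limma or edgeR, and DESeq2 called 12. Of the 27, 25 were lower adjusted over the list alone and 25 at an unadjusted p under 0.05. Mmp2, a gelatinase, averaged 35.7 ± 19.9 RPM in WT and 9.77 ± 2.56 RPM in KO (SD, n = 4 each), and Loxl1, a collagen and elastin crosslinking enzyme, averaged 16.5 ± 7.88 and 5.925 ± 1.303 RPM. All 10 tested tendon and cartilage genes were below 0, with a median of -1.25 (camera, BH adjusted p = 1.1e-11; adjusted p = 0.417 with an estimated correlation). All 10 were lower adjusted over the list alone and at an unadjusted p under 0.05. Over all genes 0 passed in limma or edgeR and 4 by DESeq2. Col11a1, a fibrillar collagen of cartilage and bone, averaged 74.8 ± 63.0 and 6.73 ± 5.49 RPM, and Fmod, a collagen-binding proteoglycan of tendon, 43.6 ± 22.5 and 16.5 ± 5.59 RPM.

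The WT libraries differed widely among themselves in these genes, and several bone genes varied with them. Col1a1, a main collagen of bone, tendon and skin chosen after its values were seen, stood at 3440, 869, 374 and 5566 RPM in WT1 to WT4 and at 159, 290, 351 and 133 RPM in KO1 to KO4. Acp5, an osteoclast phosphatase also chosen after its values were seen, stood at 130, 16.7, 4.66 and 329 RPM in WT1 to WT4 and at 0.347 to 3.52 RPM in the KO libraries. Ibsp, the gene of bone sialoprotein and likewise chosen afterwards, stood at 85.1, 15.1, 2.66 and 154 RPM and at 0.116 to 5.63 RPM. The summed RPM of 8 osteoclast genes was 228, 29.1, 11.8 and 571 in WT1 to WT4 and 1.27 to 8.02 in the KO libraries. Acp5 and Mmp9 (87.5 RPM in WT1 and 220 RPM in WT4) made up most of the sum in WT1 and WT4. Not every bone gene varied alike. Phex averaged 0.85 RPM in WT and 1.727 RPM in KO. Alpl averaged 26.4 and 15.7 RPM, although KO1 (23.9 RPM) lay above WT1 (19.1 RPM). The bone score, a mean over 7 bone genes with Phex and Alpl among them, was higher in every WT library (2.001 to 5.101) than in any KO library (0.83 to 1.79). With it as a covariate, the median log2 fold change was -0.24 for matrix genes (BH adjusted p = 0.322 by camera) and -0.30 for tendon genes (0.322), and without WT1 and WT4 it was -0.80 and -0.90, both lists past the threshold (adjusted p = 0.513 for both with an estimated correlation). Over the alternatives taken 1 at a time the adjusted p ran from 7.69e-35 to 0.417 for matrix and from 1.69e-15 to 0.417 for tendon genes.

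Immune and fibroblast genes also fell as groups. All 15 tested macrophage and other immune cell genes were below 0, with a median log2 fold change of -0.85 (camera, BH adjusted p = 1.78e-11; adjusted p = 0.417 with an estimated correlation). Of these, 12 were lower adjusted over the list alone and 12 at an unadjusted p under 0.05. Over all genes 0 passed in limma or edgeR and 3 by DESeq2. Lyz2, a lysozyme of macrophages, stood at 56.3, 47.0, 27.5 and 121 RPM in WT and 13.4 to 19.9 RPM in KO. Tyrobp, a signalling adaptor of myeloid cells, stood at 8.44, 5.14, 2.66 and 15.0 RPM and 1.34 to 2.95 RPM. The osteoclast genes followed the same order of WT libraries, with the highest sum in WT4 (571 RPM) and the lowest in WT3 (11.8 RPM). With the bone score as a covariate the macrophage median was -0.20 (camera, BH adjusted p = 0.809; adjusted p = 0.953 with an estimated correlation). Without WT1 and WT4 it was -0.55, with all 14 tested genes below 0 (camera, BH adjusted p = 1.84e-06; adjusted p = 0.581 with an estimated correlation). Over the alternatives taken 1 at a time the adjusted p ran from 2.65e-14 to 0.809. All 11 tested fibroblast and fibro-adipogenic progenitor genes were below 0, with a median of -0.74 (camera, BH adjusted p = 2.46e-11; adjusted p = 0.417 with an estimated correlation). Of these, 8 were lower adjusted over the list alone and 8 at an unadjusted p under 0.05. Over all genes 0 passed in limma or edgeR and 6 by DESeq2. Dpt, a small matrix protein of fibroblasts, averaged 61.0 ± 11.0 RPM in WT and 29.4 ± 5.83 RPM in KO (SD, n = 4 each), without overlap between the groups. Lum, a collagen-binding proteoglycan, averaged 29.5 ± 15.2 and 7.34 ± 2.66 RPM. The abundant fibroblast genes varied less between WT libraries than Col1a1 did, with Dcn at 495, 390, 464 and 563 RPM in WT and 413, 264, 291 and 202 RPM in KO. Gsn, an actin-severing protein, stood at 223, 273, 275 and 236 RPM and 222, 145, 136 and 121 RPM. With the bone score as a covariate the fibroblast median was -0.57 (camera, BH adjusted p = 1.13e-05; adjusted p = 0.953 with an estimated correlation).

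**Figure D2:**
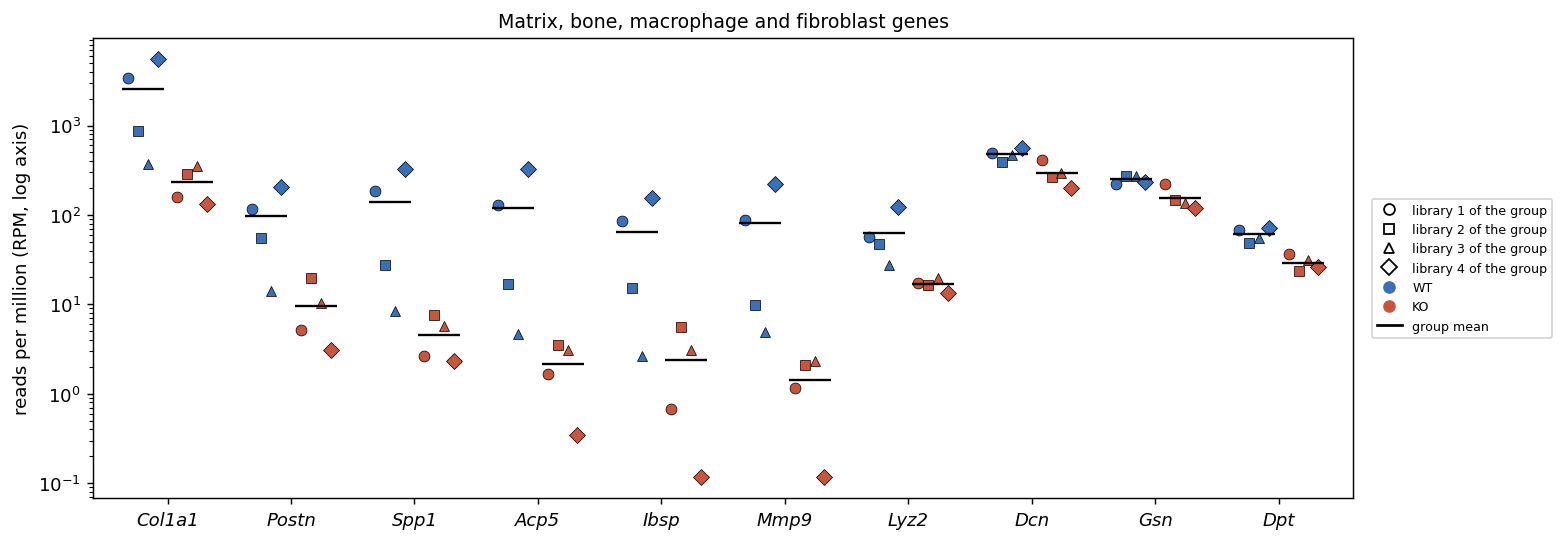
RPM on a log axis for matrix genes (Col1a1, Postn, Spp1), osteoclast and bone genes (Acp5, Ibsp, Mmp9), the macrophage gene Lyz2 and fibroblast genes (Dcn, Gsn, Dpt), with 1 point per library, the shape giving the library number, WT in blue, KO in red and a black bar at each group mean. Postn, Spp1 and Mmp9 were also chosen after their values were seen. Acp5 spans 4.66 to 329 RPM over the WT libraries, while Dpt spans 48.4 to 72.0 RPM in WT and 23.3 to 36.4 RPM in KO.

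Other cell types were examined with the same kind of lists. Of 8 tested adipocyte genes, 7 were below 0, and the list fell with a median log2 fold change of -0.50 (camera, BH adjusted p = 0.00752; adjusted p = 0.47 with an estimated correlation). Adjusted over the list alone 2 were lower, over all genes 0 in limma, edgeR and DESeq2, and 4 at an unadjusted p under 0.05. Cfd, the adipocyte serine protease adipsin, averaged 17.4 ± 5.83 RPM in WT and 7.42 ± 3.85 RPM in KO (SD, n = 4 each), Pck1 1.71 ± 0.607 and 0.507 ± 0.330 RPM, and the abundant Fabp4, a fatty acid binding protein, 229 ± 26.5 and 190 ± 24.2 RPM. Lipe, also abundant and the 1 gene of the list above 0, averaged 40.16 ± 6.139 and 43.11 ± 3.855 RPM. The median moved to -0.297 without WT2 and -0.307 without KO3, and to -0.663 without KO2. The call was lost without WT2 (adjusted p = 0.111; over the alternatives taken 1 at a time 1.36e-06 to 0.47). The endothelial list had a median of -0.10 (camera, BH adjusted p = 0.521), with 1 of 14 genes lower adjusted over the list alone, 2 at an unadjusted p under 0.05 and 0 over all genes in limma, edgeR and DESeq2. The receptor phosphatase Ptprb averaged 61.7 ± 4.81 and 44.7 ± 3.36 RPM, and Pecam1 176 ± 25.5 and 154 ± 23.9 RPM. The abundant Cdh5, 1 of 3 endothelial genes above 0, averaged 65.18 ± 6.672 and 76.43 ± 4.451 RPM. The smooth muscle and pericyte list (median -0.11, adjusted p = 0.555), the Schwann cell and nerve list (-0.14, 0.860) and the muscle stem cell and regeneration list (-0.12, 0.258) did not pass camera's BH threshold. In these 3 lists 0 genes passed in limma, edgeR or DESeq2 or adjusted over the list alone, and 0, 0 and 2 had an unadjusted p under 0.05. Igf1, a growth factor in the stem cell list, averaged 6.96 ± 1.42 and 3.82 ± 1.32 RPM. Acta2 of the smooth muscle list averaged 10540 RPM in WT and 9903 RPM in KO. Both it and its close paralog Acta1 (25010 and 23860 RPM) were named after their values were seen. The level of Acta2 is uncertain, since the sources do not say how reads shared by paralogs were counted. The single tested erythroid gene, Alas2, averaged 10.6 ± 3.43 and 9.08 ± 4.05 RPM.

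Contractile genes of slow fibres, which are scarce in the TA muscle, rose as a list in the KO. Of 12 tested genes 9 were above 0, with a median log2 fold change of 0.28 (camera, BH adjusted p = 0.000418; adjusted p = 0.756 with an estimated correlation). Adjusted over the list alone 2 were higher, Myl2 and Tnnc1, over all genes 0 in limma, edgeR and DESeq2, and 3 at an unadjusted p under 0.05. Myl2, the slow regulatory light chain of myosin, stood at 34.4, 38.1, 33.0 and 65.3 RPM in WT1 to WT4 and at 56.5, 163, 54.8 and 292 RPM in KO1 to KO4. Tnnc1, slow troponin C, stood at 4.17, 4.14, 2.53 and 4.51 RPM and at 11.4, 18.7, 3.47 and 66.4 RPM. Tnni1, slow troponin I, chosen after its values were seen, ranged from 9.05 to 20.8 RPM in WT and stood at 19.2, 41.8, 9.04 and 161 RPM in KO. KO4 and KO2, both female, thus held the highest levels of all 3 genes. Both also retained the most Sdhc among the KO libraries (54.3 and 46.5 RPM). The mean log2(RPM + 1) of the list was higher in females of both groups. It was 4.273, 5.377, 4.356 and 5.161 in WT1 to WT4 and 4.856, 5.703, 4.543 and 6.197 in KO1 to KO4. The median log2 fold change was 0.346 in males and 0.285 in females (interaction of genotype and sex by camera, BH adjusted p = 0.424). The list's call was lost without WT3 (adjusted p = 0.0749; over the alternatives taken 1 at a time 2.77e-07 to 0.82). The median ranged from 0.06 without WT1 to 0.57 without WT2, and was 0.14 without KO2 or KO4 and 0.52 without KO1. Fast fibre genes had a median of 0.04 over 16 genes (camera, BH adjusted p = 0.11), with Actn3 at 8172 ± 723 and 9212 ± 611 RPM (SD, n = 4 each) and Tnni2 at 17690 ± 1700 and 19670 ± 1678 RPM. Genes of calcium handling and excitation-contraction coupling had a median of 0.05 over 24 genes (adjusted p = 0.0525). The chloride channel gene Clcn1 averaged 161 ± 17.7 and 191 ± 15.8 RPM. The denervation and neuromuscular junction list had a median of 0.01 and a mean of -0.08 over 17 genes (adjusted p = 0.737). Runx1, a transcription factor induced by denervation, stood at 11.9 ± 6.22 and 5.85 ± 1.43 RPM and Dok7 at 28.2 ± 5.07 and 21.2 ± 6.73 RPM. In these 3 lists 0 genes passed in limma, edgeR or DESeq2 or adjusted over the list alone, and at an unadjusted p under 0.05 there was 1, in the junction list.

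**Figure D3:**
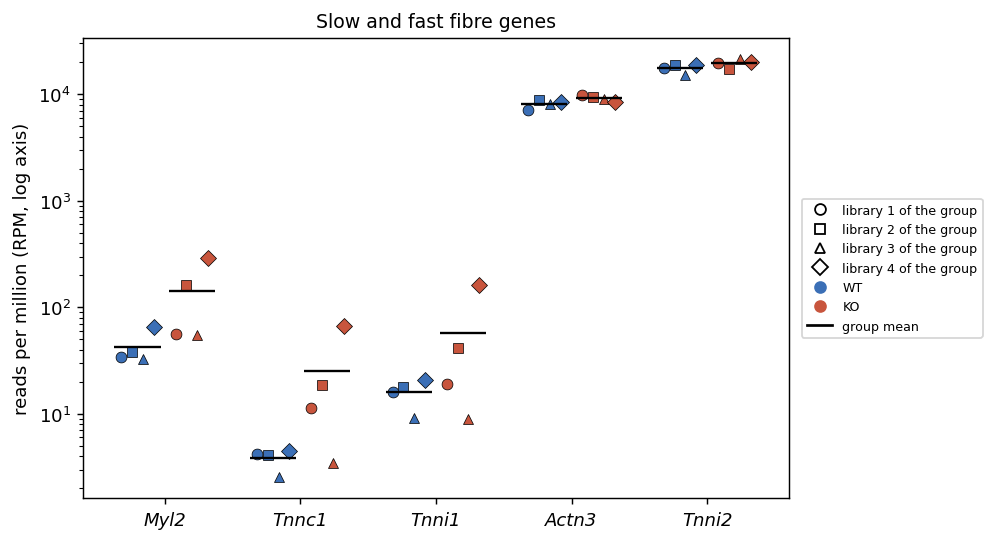
RPM on a log axis for 3 slow fibre genes (Myl2, Tnnc1, Tnni1) and 2 fast fibre genes (Actn3, Tnni2), with 1 point per library, the shape giving the library number, WT in blue, KO in red and a black bar at each group mean. KO4 (diamond) reaches 292 RPM for Myl2 and 161 RPM for Tnni1, while Tnni2 stays between 15258 and 21536 RPM in all 8 libraries.

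Nuclear genes of mitochondrial energy metabolism differed little in size. Fatty acid uptake and oxidation genes had a median log2 fold change of 0.10 over 24 genes, 17 of them above 0 (camera up, BH adjusted p = 0.0226; adjusted p = 0.756 with an estimated correlation). The median was 0.07 for 31 complex I genes, 21 above 0, and 0.05 for 18 enzymes of the TCA cycle other than SDH, 13 above 0 (both camera up, BH adjusted p = 0.0447; adjusted p = 0.756 with an estimated correlation). It was 0.01 for 69 mitochondrial ribosome genes, 38 above 0 (camera up, BH adjusted p = 0.0396; adjusted p = 0.756 with an estimated correlation). Leaving out 1 library gave fatty acid medians from -0.012 (without WT1, 14 of 24 genes below 0) to 0.256 (without WT2). The medians ran from -0.005 (without WT1) to 0.139 (without WT3) for complex I, from 0.011 (without KO2) to 0.10 (without WT3) for the TCA list, and from -0.012 (without WT1 or WT4) to 0.059 (without WT3) for the mitochondrial ribosome. In these 4 lists 0 genes passed over all genes in limma, edgeR or DESeq2, 0 passed adjusted over the list alone, and at an unadjusted p under 0.05 there was 1 in each of the last 3 and 0 in the first. The complex I gene with the smallest p was Ndufb11, lower while most of its list lay above 0, at 1073 ± 205 RPM in WT and 755 ± 28.7 RPM in KO (SD, n = 4 each). In the TCA list Pdhb, a subunit of pyruvate dehydrogenase, averaged 224 ± 67.2 and 335 ± 87.7 RPM. Angptl4, a lipase inhibitor in the fatty acid list, averaged 1.70 ± 1.16 and 0.621 ± 0.677 RPM. Eci2 of the same list went the other way, at 60.91 ± 10.64 and 71.72 ± 1.804 RPM. Mrps27 of the mitochondrial ribosome averaged 25.01 ± 5.623 and 32.6 ± 5.38 RPM. Without WT1 and WT4, the libraries with the highest osteoclast sums (228 and 571 RPM), camera put the complex I and fatty acid lists down (adjusted p = 0.791 for both) and none of the 4 passed. Lists of complex III (median -0.03, adjusted p = 0.828), complex IV (0.01, 0.767), complex V (0.02, 0.347), mitochondrial chaperones and proteases (0.07, 0.0509), and mitochondrial biogenesis and dynamics (0.02, 0.202) did not pass camera's BH threshold. Of their genes 0 passed in limma, edgeR or DESeq2 or adjusted over the list alone, and 1, in complex IV, had an unadjusted p under 0.05. Cox6a1 of complex IV averaged 154 ± 18.0 and 116 ± 19.9 RPM, and Pink1, a kinase that marks damaged mitochondria, 526 ± 59.9 and 592 ± 45.7 RPM.

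Pathways tied to succinate and to mitochondrial stress were examined next, and none of their lists passed camera's BH threshold. Succinate, the substrate of SDH, is known to inhibit enzymes that use 2-oxoglutarate, including the prolyl hydroxylases that control hypoxia-inducible factor. The targets of that factor had a median log2 fold change of -0.03 and a mean of 0.05 over 24 genes (adjusted p = 0.254), and the 2-oxoglutarate dioxygenase genes a median of -0.06 over 26 genes (adjusted p = 0.935). In the first of these lists 1 gene had an unadjusted p under 0.05 and in the second 2, and 0 passed in limma, edgeR or DESeq2 or adjusted over the list alone. Pfkfb3, which makes an activator of glycolysis, stood at 16.7 to 40.3 RPM in WT and at 42.8, 50.1, 297 and 46.3 RPM in KO1 to KO4. Pfkfb4 of the same list went the other way, averaging 2.28 ± 0.6505 RPM in WT and 1.432 ± 0.7024 RPM in KO. The demethylase gene Kdm4c averaged 12.5 ± 5.23 and 19.3 ± 6.10 RPM (SD, n = 4 each), and Plod2, a collagen lysyl hydroxylase, 9.54 ± 6.86 and 3.48 ± 1.12 RPM. Genes of the integrated stress response had a median of -0.01 over 28 genes (adjusted p = 0.975), 1 of them at an unadjusted p under 0.05 and 0 past the threshold in limma, edgeR or DESeq2 or adjusted over the list alone. The amino acid transporter gene Slc7a5 averaged 2.27 ± 0.469 and 1.29 ± 0.745 RPM. Fgf21 and Gdf15, cytokines released by muscle under mitochondrial stress and chosen after their values were seen, lay below the 3-read floor in every library, so a difference was not detectable at this depth. The NRF2 and antioxidant list had a median of -0.09 over 26 genes (adjusted p = 0.555), with Gpx3 as its 1 gene past the threshold over all genes in limma and adjusted over the list alone. In this list edgeR called 0 genes and DESeq2 1, and 3 had an unadjusted p under 0.05.

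Genes of glycolysis, growth and muscle wasting did not pass camera's BH threshold as lists either. Glycolysis and lactate genes had a median of 0.03 over 22 genes (adjusted p = 0.159), with Ldhb, the heart-type lactate dehydrogenase, at 52.3 ± 14.0 and 68.1 ± 14.3 RPM (SD, n = 4 each). Genes of pyruvate carboxylation, aspartate and glutamine had a median of -0.02 over 20 genes (0.789), with the transaminase Gpt2 at 86.6 ± 12.7 and 108 ± 12.6 RPM. Muscle atrophy and proteolysis genes had a median of -0.07 over 25 genes (0.913), with Foxo4, a transcription factor of the atrophy programme, at 107 ± 19.7 and 134 ± 6.78 RPM and Eda2r at 16.5 ± 1.55 and 14.0 ± 2.53 RPM. Protein synthesis and growth signalling had a median of -0.02 over 21 genes (0.789), with Myc at 6.40 ± 2.25 and 3.52 ± 1.68 RPM and Fst, an inhibitor of myostatin, at 2.72 ± 1.12 and 1.42 ± 0.525 RPM. The medians and adjusted p-values of the other lists were 0.01 and 0.194 (proteasome), 0.04 and 0.326 (cytosolic ribosome), -0.16 and 0.326 (sterol and fatty acid synthesis), 0.06 and 0.431 (p53 and cell cycle arrest), -0.03 and 0.666 (interferon response), -0.06 and 0.925 (circadian clock) and -0.07 and 0.927 (immediate early and heat shock). In the clock list Nr1d1 averaged 101 ± 23.9 and 135 ± 20.3 RPM and Per1 106 ± 15.8 and 79.6 ± 12.5 RPM. In these 11 lists 0 genes passed over all genes in limma, edgeR and DESeq2 and 0 passed adjusted over the list alone, with 0 to 4 genes per list at an unadjusted p under 0.05. Camera compares the moderated test statistics of each list with those of all other genes, and the median log2 fold change of all tested genes was -0.05. The direction by camera was up for the hypoxia, pyruvate, atrophy, growth signalling, interferon and clock lists although their medians were below 0. It was also up for complex II, complex IV and the neuromuscular junction although their means were below 0. The atrophy and clock medians lay below -0.05 as well, so the overall median does not account for every direction.

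**Figure D4:**
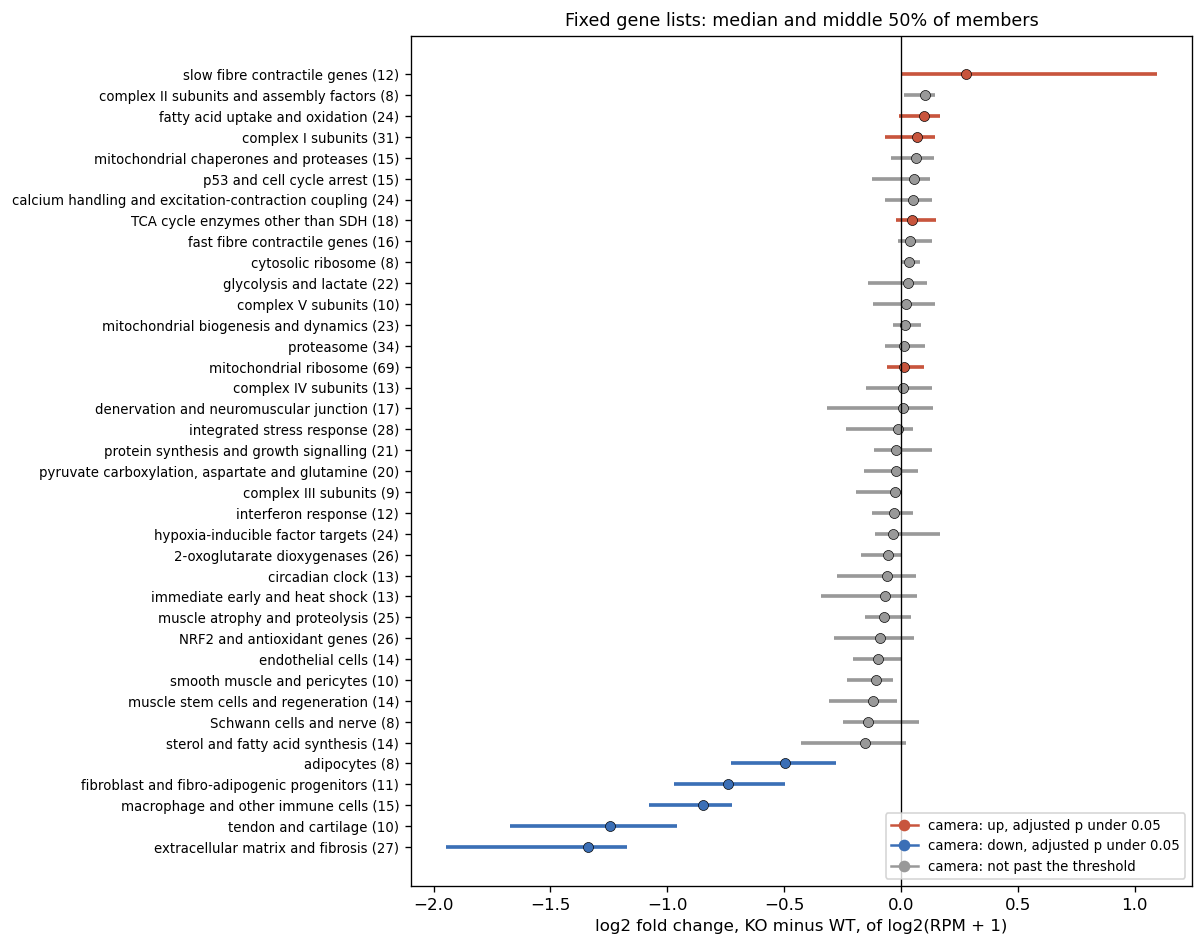
Median log2 fold change (KO minus WT, log2(RPM + 1) scale) of each of the 38 tested gene lists as a point, with a line over the middle 50% of its members and the number of tested genes in brackets. Lists past camera's threshold are red (up) or blue (down) and the others grey; matrix genes have the lowest median at -1.34 and slow fibre genes the highest at 0.28, and 0 of the lists pass with an estimated correlation.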

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

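Among the tests of this part, those on the matrix genes without WT1 and WT4, on the osteoblast sum without single genes, on the matrix and fibroblast genes with the bone score, on the position and depth of the targets with high and low libraries, on the splits balanced for sex, and on the interaction of genotype and sex were chosen only after the results had been seen. The osteoblast, osteoclast and granulocyte lists were written after the matrix genes had been seen.

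Matrix and tendon genes were lower in the KO libraries, and bone attached to some WT muscles may account for part of this. The summed RPM of the osteoblast and osteocyte genes was 8.25 times higher in WT4, the WT library with the highest matrix score, than in WT3, the lowest (108, 46.6, 24.1 and 199 RPM in WT1 to WT4, 12.4 to 27.9 RPM in KO), but the ratio rests on few genes: it was 32.41 without Alpl and 2.08 without Ibsp, where WT1 (22.7 RPM) lay below KO1 (27.2 RPM). The sum of the bone marrow granulocyte genes did not decide on marrow. It was 2.13 to 6.94 RPM in WT and 1.04 to 4.34 RPM in KO, with KO1 above WT1 to WT3. Much of it was Lcn2 (4.178 RPM in KO1, 4.751 RPM in WT4). Ngp was highest in WT1 and WT4 (0.987 and 1.34 RPM, at most 0.248 RPM elsewhere), as was Camp (0.548 and 0.609 RPM, at most 0.231 RPM elsewhere). Elane and Ctsg did not follow this order, and Mpo was at 0 in all 8 libraries. These values rest on few reads, so marrow stays open. With the bone score as a covariate the matrix median shrank from -1.34 (middle 50% of genes -1.95 to -1.17, median SE 0.38) to -0.24 (-0.39 to -0.06, median SE 0.30), which ended the call, but all WT scores (2.001 to 5.101) lay above all KO scores (0.83 to 1.79), so the score would absorb an effect of genotype too. WT1 and WT4 are not the whole source, since without them the matrix median was still -0.802, although WT2 and WT3 also held more osteoclast RPM than any KO library (29.1 and 11.8 against at most 8.02), and an effect of genotype stays open.

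Fibroblast genes were also lower in the KO libraries, and bone and genotype cannot be told apart for them, because the bone score separates the groups completely; the rule written for excluding bone was met, and the exclusion was withdrawn afterwards for this reason. With the bone score as a covariate the fibroblast median moved from -0.74 (middle 50% -0.97 to -0.50) to -0.57 (-0.69 to -0.44) while the median SE rose from 0.20 to 0.30, and the list passed camera with BH adjustment at the preset correlation (adjusted p = 1.13e-05; adjusted p = 0.953 with an estimated correlation). Without WT1 and WT4, where the mean bone score of WT over KO shrank from 2.057 to 0.883, the median was -0.72 (adjusted p = 2.6e-10; adjusted p = 0.513 with an estimated correlation). A lower share of fibre RNA in the WT libraries would raise every other cell type alike, but the 14 endothelial genes lay 0.694 above the 11 fibroblast genes in mean log2 fold change (permutation test over genes, two-sided, 100000 resamples, p = 3e-05; genes are not independent replicates). Fewer fibroblasts or lower fibroblast expression in the KO muscle may remain as a hypothesis beside bone, as may other connective tissue left on the WT muscles, which was not tested.

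For 8 targets the libraries fell into a high and a low set far apart, in 4 patterns that did not follow the groups. Of these, 5 were read well in WT2, WT4 and KO4 and hardly at all elsewhere: Srsf10 (31.1 to 35.8 RPM against at most 0.768), Padi2 (52.4 to 105 against at most 0.248), Zfp933 (3.13 to 6.09 against 0), Fv1 (8.71 to 9.49 against at most 0.124) and Gpr157 (30.9 to 43.5 against at most 0.932). All 5 lie on chromosome 4 between 135855747 and 150105927 (GRCm38), a span of 14.3 Mb, and 0 of 100000 random draws of 5 from 10607 located targets fell as close (share 1e-05, the smallest the draws can give). Depth is excluded for these 5, since the median number of reads expected in the other 5 libraries was 232.2 (23.5 to 393.6). A chromosome segment from another strain, with sequence variants under the amplicon or with different expression, is a candidate explanation, and no biological explanation tied to the groups was tested.

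The counts of the main comparison were set against other splits of the 8 libraries into 4 and 4. As many genes as the real 3 were called in 2 of 35 splits, the real one included, so chance could not be excluded for this count. The highest other split, males against females, gave 46 genes, which points to sex as a structure of the samples and is a real contrast. Of the 18 splits with 2 males on each side, only the real one gave 3 genes and the highest other gave 0, but 18 splits are too few for a share under 0.05. As many lists as the real 10 were called in 6 of 35 splits, with 12 in the highest other (11 among the splits balanced for sex), so chance could not be excluded for the list count either. Every other split with as many lists put WT1 and WT4, the libraries with the highest bone scores (4.264 and 5.101), on the same side. These splits thus hold a structure of the samples too, and they cannot tell how many lists chance alone would give.

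In single groups of 4, 13 of 284 values had 1 library far from the other 3 by Dixon's ratio of gap to range, where chance gives about 14. WT1 stood apart for Bbc3 (1.65 RPM against 1.07 to 1.14, ratio 0.866), Dok7 (20.6 against 30.3 to 31.1, ratio 0.924) and the scores of the Schwann cell list (2.71 against 3.34 to 3.36, ratio 0.968) and the p53 list (4.71 against 4.96 to 4.98, ratio 0.917), each score being a mean log2(RPM + 1). WT4 stood apart for Fst (4.39 RPM against 1.996 to 2.285, ratio 0.879), Junb (24.5 against 12.2 to 13.6, ratio 0.889), Myl2 (65.3 against 33.0 to 38.1, ratio 0.841) and Tgfb3 (128 against 99.1 to 103, ratio 0.858). KO2 stood apart for Kdm4c (10.3 RPM against 21.6 to 23.5, ratio 0.859) and the mitochondrial biogenesis score (6.03 against 5.84 to 5.86, ratio 0.897). KO3 stood apart for Pfkfb3 (297 RPM against 42.8 to 50.1, ratio 0.971), and KO4 for the scores of protein synthesis (5.04 against 5.25 to 5.26, ratio 0.950) and of matrix genes (3.69 against 4.41 to 4.52, ratio 0.872).

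An interaction of genotype and sex was tested on 2 animals per sex and group. The KO females retained 5.84 and 6.82% of the WT mean of Sdhc and the KO males 2.12 and 2.35%. Sex and the degree of Sdhc loss therefore cannot be told apart within the KO group. At an unadjusted p under 0.05 there were 513 genes, fewer than the 550 that chance gives. By limma with BH adjustment 4 genes passed: Ddit4, an inhibitor of mTORC1 signalling, together with Gadd45g, Cebpd and 8430408G22Rik, all 4 named after their values were seen. Ddit4 stood at 942 and 579 RPM in KO males against 93.4 and 186 RPM in WT males, and at 57.8 and 33.7 RPM in KO females against 110 and 254 RPM in WT females (interaction -4.37 on the log2 scale, adjusted p = 0.0285). Gadd45g stood at 911 and 724 RPM in KO males and 147 and 91.1 RPM in KO females, against 185 to 472 RPM in WT. By camera, the interaction passed for the matrix list (BH adjusted p = 2.36e-12; median log2 fold change -0.74 in males, -2.05 in females), the fatty acid list (0.000163; 0.29, -0.05), the macrophage list (0.000163; -0.51, -1.17), the fibroblast list (0.000163; -0.51, -1.02) and the tendon list (0.00075; -0.74, -1.73). None of the 5 passed with an estimated correlation (adjusted p = 0.923 for each). The bone score was 2.668 and 5.101 in WT females against 1.78 and 0.83 in KO females. In males it was 4.264 and 2.001 in WT against 1.4 and 1.79 in KO. The groups thus lay further apart in females, as they did for the matrix, macrophage, fibroblast and tendon lists. For these lists bone and an interaction of genotype and sex cannot be told apart.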

How the results depend on the processing

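In this part, the comparison without WT1 and WT4, the fit with the bone score, and the naming of genes called only by DESeq2 or without WT3 were chosen only after the results had been seen. Sdhc kept its direction and its call under all alternatives, with log2 fold changes of -4.97 to -4.42. Of 104 named genes followed over 29 alternatives, 83 never changed their call. The causes of the changes below were not tested, except that leaving out libraries also lowers the number of samples. Depth limits genes near 0.5 RPM, and the simulations above show that most 1.5-fold changes of genes with at least 5 RPM would be missed with 4 libraries per group.

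The count of 3 genes was 1 under median-ratio, TMM and quantile scaling, without the intensity trend, in edgeR, without WT1 and WT4, and with the bone score as a covariate, in each case Sdhc. It was 149 in DESeq2 (4 higher: Cog6, Ppp1r14c, Stbd1 and Ginm1) and 168 at an unadjusted p under 0.05 with a 2-fold change. Leaving out 1 library gave 1 to 130 genes, with 130 without WT3 (1 higher, Wdfy2), 10 without KO1 and 1 without any of the others. Library weights and sex as a term each gave 4 genes, adding Dpt (adjusted p = 0.046 and 0.0453 by limma with BH). The chaperone and calcium handling lists passed camera under a pseudocount of 5 RPM (0.0487 and 0.0488), median-ratio scaling (0.0109 and 0.033), TMM scaling (0.0125 and 0.0367) and edgeR (0.0254 and 0.0405), and without KO4 (0.0333 and 0.0489), and the chaperone list also without KO3 (0.0299). The fast fibre list passed without WT1 (0.0161), without KO1 (0.0288), without both WT1 and WT4 (0.000321) and with the bone score (0.000542).

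The count of 10 lists was 4 with the filter at 10 RPM, 6 under quantile scaling, 4 with the bone score, 0 with an estimated correlation, 0 by fry in one direction and 1 by fry in either direction (complex II, adjusted p = 0.000306, with Sdhc in it). The count rose under median-ratio and TMM scaling and in edgeR, where the 10 lists kept their calls and the chaperone and calcium handling lists passed too. By fry in one direction the adjusted p was 0.164 for the matrix, tendon, macrophage, fibroblast and adipocyte lists, 0.82 for slow fibre, 0.911 for complex I, TCA and fatty acid, and 0.923 for mitochondrial ribosome genes. In either direction it was 0.0869 (matrix, macrophage), 0.0838 (tendon, adipocyte), 0.0584 (fibroblast), 0.652 (slow fibre), 0.788 (complex I), 0.662 (TCA), 0.839 (fatty acid) and 0.879 (mitochondrial ribosome). With an estimated correlation it was 0.417 for matrix, tendon, macrophage and fibroblast, 0.47 for adipocyte, and 0.756 for slow fibre, fatty acid, TCA, complex I and mitochondrial ribosome genes.

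The mitochondrial lists lost their camera calls most often. Adjusted p-values (BH over lists) for complex I were 0.107 without a filter, 0.197 with the filter at 10 RPM, 0.933 under quantile scaling, 0.0567 without the trend, 0.0584 with library weights and 0.0529 with sex as a term. For the TCA list they were 0.102, 0.17, 0.695, 0.0567 and 0.0584 under the first 5 of these. For the fatty acid list they were 0.0681 with the filter at 10 RPM, 0.424 under quantile scaling and 0.0584 with library weights. For the mitochondrial ribosome they were 0.107 without a filter, 0.325 with the filter at 10 RPM and 0.424 under quantile scaling. The adipocyte list gave 0.106 with the filter at 10 RPM, where too few macrophage genes were left to test that list. Without WT1 and WT4 the direction turned down for complex I (0.791) and fatty acid genes (0.791), and the calls of the TCA (0.534) and mitochondrial ribosome lists (0.806) were lost. With the bone score it turned down for complex I (0.712), fatty acid (0.805) and mitochondrial ribosome genes (0.712), and the calls of the TCA (0.809), matrix (0.322), tendon (0.322) and macrophage lists (0.809) were lost. Leaving out 1 library gave ranges of 0.00632 to 0.291 (complex I), 0.0146 to 0.164 (TCA), 1.42e-07 to 0.394 (fatty acid), 0.0085 to 0.295 (mitochondrial ribosome), 4.77e-07 to 0.0749 (slow fibre, highest without WT3) and 0.00196 to 0.111 (adipocyte, highest without WT2). The calls were lost without WT1, WT4, KO1, KO2 or KO3 for complex I and TCA, without WT1, WT3 or KO1 for fatty acid, and without WT1, WT4, KO1 or KO2 for mitochondrial ribosome genes.

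With the replicate number as a block the gene count was 1, 9 lists passed, and complex I had an adjusted p of 0.0512. The numbers do not pair the samples by the data: correlations of the residuals of same-numbered libraries were 0.003, 0.257, 0.125 and 0.105, and 2 of 8 libraries correlated best with their own number.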

Other observations

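The comparison of sexes in this part and the genes named in it were chosen only after the results had been seen. With sex and genotype as terms, limma with BH adjustment called 61 genes between the 4 female and 4 male libraries besides the 5 genes used to read sex, 24 higher in females and 37 higher in males. Of the 61, 57 were also called by edgeR, which called 70. Higher in females were H19, an imprinted noncoding RNA, which averaged 252 ± 63.7 RPM in males and 1020 ± 169 RPM in females (SD, n = 4 each, log2 difference 2.04, SE 0.15, adjusted p = 3.88e-06), Meg3, at 83.4 ± 9.90 and 202 ± 33.1 RPM (adjusted p = 0.000375), and Rian, at 56.3 ± 5.73 and 118 ± 13.0 RPM (adjusted p = 0.00101). Csrp3, a Z-disc protein of the slow fibre list, was also higher in females (adjusted p = 0.0064), at 25.55 to 38.78 RPM in males and at 409, 109, 101 and 111 RPM in WT2, WT4, KO2 and KO4. Myoz2, another Z-disc protein of that list, averaged 78.4 ± 13.7 and 153 ± 40.3 RPM (adjusted p = 0.0424). Higher in males were Mgst1, a membrane glutathione transferase, at 63.0 ± 8.42 RPM against 16.7 ± 3.69 RPM (adjusted p = 3.88e-06), Actr3b, an actin-related protein, at 53.1 ± 19.7 against 6.86 ± 2.61 RPM (adjusted p = 2.18e-05), and Mettl21c, a methyltransferase of muscle, at 59.0 ± 9.97 against 21.6 ± 7.79 RPM (adjusted p = 0.000374). Srsf10 and Gpr157 are among the 61 and stood at 30.9 RPM or more in 3 of the 4 female libraries and at 0.932 RPM or less in the other 5 libraries, as given above with the chromosome 4 targets.

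Among the targets with high and low libraries, those outside chromosome 4 had patterns of their own. Echdc3 was read in WT4 (7.31 RPM) and KO1 (9.69 RPM) and stood at 0.799 RPM or less in the other 6 libraries. Etfdh, an enzyme that passes electrons from fatty acid oxidation to the respiratory chain, stood at 8.92 RPM in WT3 and 8.16 RPM in KO2 and at 44.2 to 51.5 RPM in the others. Slc15a5 stood at 13.71 to 25.02 RPM in the 4 males and at 0.422 to 1.04 RPM in the 4 females.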
